A study of Bdellovibrio bacteriovorus HD100 with 6 samples.

How the data were processed

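Messenger RNA of Bdellovibrio bacteriovorus HD100 was measured in 6 libraries, 3 from cells kept in HEPES buffer and 3 from cells kept with a Staphylococcus aureus biofilm. Per the labels' protocols, predator cultures raised on Escherichia coli MG1655 in HEPES with 4 mM CaCl2 and 2 mM MgCl2 were passed through a 0.45 µm filter before the mixing and again after 4 h at 30 °C, the second time to take away S. aureus. RNA was made into single-end libraries of 50 bp reads with a TruSeq mRNA kit, per the labels' protocols. The aligner, the counting program, the genome build, the removal of ribosomal RNA and the use of strand are not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

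The deposited count table holds whole reads per gene with no normalization by the authors. It lists 3584 genes of 1 chromosome with coordinates and annotation text, of which 1632 have a product called hypothetical. The annotation text of 224 genes was not used here. Gene lengths are multiples of 3 for 99.0% of genes, so they are coding lengths. The deposited RPKM table gives RPKM, reads scaled by gene length and library total, as the authors computed them. Compared with the counts, its values imply a length shorter than the gene by 141 to 160 nt in the 6 libraries. The deposited RLE and TMM signal tables hold the counts multiplied by 1 factor per library, as their constant ratio to the counts shows. The TMM factors of the authors' table were 2.36, 2.33 and 2.08 in HEPES and 0.625, 0.602 and 0.711 with the biofilm. The deposited tables used here hold no fold changes, so the planned comparison with such values had nothing to compare.

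Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at its defaults, scaled by TMM, fitted with glmQLFit on the group alone and tested with glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the 3090 genes kept. A gene was called at an adjusted p under 0.05, and a second count asked for a change of at least 2-fold. Levels are given as CPM, the count scaled by the library total and the TMM factor, with the mean and SD over 3 libraries. Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation, camera on ranks and fry. Of 34 lists fixed by product name or symbol, 29 had at least 5 tested members, 3 were smaller and 2 matched no gene. The 2 without a match were a list of known predation genes, which uses another numbering of locus tags, and a list of E. coli or S. aureus features.

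The design, the alternatives and the rule for genes named in the text were fixed before the data were examined. The rule took called genes with a mean of at least 10 CPM and no overlap between the groups. Among these it named the 8 highest and 8 lowest log2 fold changes with a known product, the 2 highest and 2 lowest without one, up to 3 called members per list and direction by p, and the 3 most abundant genes of each group. It gave 152 genes. The text names 41 of them, chosen after their values were seen from the 125 that were called in the same direction under all 6 scalings. Of these 41 genes, 11 overlap a neighbour on the same strand by at most 14 nt and 0 overlap a gene on the other strand. The 6 flagellin genes are related copies whose reads the counting could split wrongly.

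Alternatives were RLE and upper-quartile factors, no or a stricter low-count filter, the replicate number as a block, the rRNA and tRNA genes or the 10 most abundant genes left out, each library and each replicate number left out, DESeq2 1.42.0, and limma on log2 of the deposited RPKM plus 1 or 0.1. Further scalings by library size alone, by the factors of the deposited TMM table and by RNase P RNA, and thinning to the smallest total, were chosen after seeing the data. On simulated counts with the real levels and totals for this comparison, with 3075 genes kept, edgeR called 77.1% of 96 genes changed 2-fold, 99.0% of 96 genes changed by 2 on the log2 scale and 0.42% of 2883 unchanged genes. With 3040 genes kept, camera called the simulated list that had moved and 0 of the other lists. Simulated levels were averaged over both groups, genes were drawn independently, and only 200 genes, equally up and down, or 1 list were changed. In the real data 73.9% of genes were called, so these rates need not carry over to them. Replicates differed by more than counting noise in every pair, with a chi-square per degree of freedom of 5.93 to 119, so no pair was 1 library counted again with counting noise alone. This does not show separate cultures. They were used as separate samples because the labels list them so.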

Results

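The libraries measured messenger RNA of Bdellovibrio bacteriovorus HD100, a small predatory bacterium that enters other Gram-negative bacteria and grows inside them. Predator cells were kept for 4 h in HEPES buffer or with a biofilm of Staphylococcus aureus, a Gram-positive species outside its prey range, and 3 libraries were made of each. The comparison asked how the predator's transcripts differ between buffer and a biofilm that it does not prey on. All 6 libraries were taken after 4 h, so rose and fell mean only higher and lower with the biofilm than in HEPES. Reads assigned to genes numbered 10017380 to 11987776 per library in HEPES and 12142450 to 15078926 with the biofilm. Of 3584 genes, 3421 had a read in at least 1 library, and 0 of the 42 rRNA and tRNA genes had one. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

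With the biofilm, 38 of 42 tested flagellum genes and 43 of 50 ribosomal protein genes were higher. Camera called both lists (Benjamini-Hochberg adjusted p = 1.74e-18 and 0.0241), but not with an estimated correlation (adjusted p = 0.829 and 0.911). Transcripts of flhA, whose product forms the gate of the flagellar export apparatus, rose from 50.9 ± 7.76 to 1563 ± 146 normalised CPM (mean ± SD, n = 3 per group). The periplasmic protease gene BD_RS11995 rose from 10.3 ± 0.758 to 603.9 ± 165 CPM. The chaperone gene dnaK fell from 22510 ± 1746 to 1706 ± 340 CPM, and the gene of the periplasmic stress protein CpxP, BD_RS04055, fell from 52669 ± 2219 to 4251 ± 1299.

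By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2282 of 3090 genes (73.9%) were called, 1306 higher and 976 lower with the biofilm. At least a 2-fold change was reached by 1906 genes, 1145 higher and 761 lower. The split depended on the scaling. It was 923 higher and 1341 lower with upper-quartile factors, 2022 and 467 against RNase P RNA, and 2299 and 332 by library size alone, where the median gene moved by -0.69, 1.07 and 1.53 on the log2 scale relative to TMM. In the same direction under all 6 scalings, 1255 genes were called, 923 higher and 332 lower, and each gene named here by symbol or locus tag is among them. These 2 counts equal those higher with upper-quartile factors and lower by library size alone. Relative to TMM the scalings reach further up (1.53) than down (-0.69). Being called under all 6 is therefore a stricter demand on falls than on rises, in the lists below too. The SEs given below are for the TMM fit and do not include this shift between scalings.

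**Figure D1:**
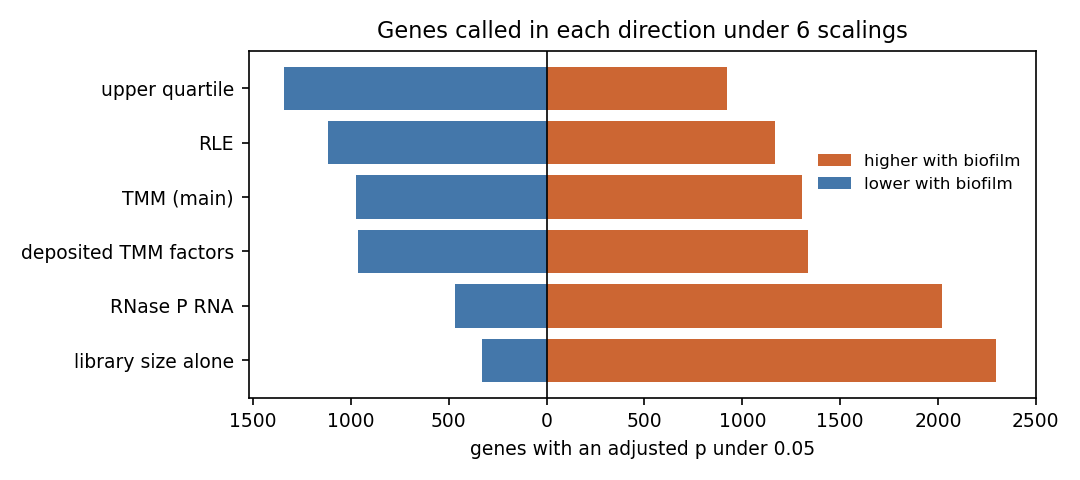
Horizontal bars give the number of genes with an adjusted p under 0.05 under 6 scalings of the same libraries, to the right for genes higher with the biofilm and to the left for genes lower with it. The 2 bars run from 923 higher and 1341 lower with upper-quartile factors to 2299 higher and 332 lower by library size alone.

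Of the 42 flagellum genes tested, 38 rose and 3 fell, with a median log2 fold change of 3.95 that stayed between 3.24 and 5.47 under the 6 scalings. Under all of them 37 rose and 3 fell. Camera called the list (Benjamini-Hochberg adjusted p = 1.74e-18), and the adjusted p was 0.829 with an estimated correlation. On chromosome 1, flhA (3235898 to 3237997, minus strand) and the export gene fliP (BD_RS15220, 3240151 to 3240909, minus strand) had log2 fold changes of 4.94 (SE 0.17) and 4.67 (SE 0.17), with adjusted p of 5.67e-12 and 6.25e-12 by edgeR's quasi-likelihood test. The flagellin gene BD_RS13980 (2960612 to 2961445, plus strand) rose by 3.88 (SE 0.18) to 13482 ± 2262 CPM, among the 3 most abundant genes with the biofilm. Another flagellin gene, BD_RS02750 (562130 to 562954, plus strand), fell by 3.07 (SE 0.16) from 14703 ± 489 to 1752 ± 264 CPM. Reads can be misassigned between flagellin copies. A fliL gene, BD_RS04950, fell by 1.96 (SE 0.14), and BD_RS04040, annotated with the symbol fliG of the motor switch, fell by 2.03 (SE 0.15). Over the 6 scalings their log2 fold changes ran from -2.64 to -0.42 and from -2.71 to -0.49, far wider than the SEs.

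Of 27 chemotaxis genes, 18 rose and 6 fell, 16 and 2 of them under all 6 scalings. A gene annotated as CheY (BD_RS15375) and a methyl-accepting receptor gene (BD_RS04975) rose by 4.04 (SE 0.18) and 3.36 (SE 0.15), while the chemotaxis gene BD_RS11970 fell by 4.09 (SE 0.23) and the cheW gene BD_RS15870 fell by 2.00 (SE 0.14). In the type IV pilus list, 8 genes rose and 6 fell of 14, 7 and 2 of them under all 6 scalings. The risers included pilC (BD_RS06850, 1432713 to 1433930, plus strand) at 5.05 (SE 0.19) and pilT (BD_RS06845, 1431668 to 1432711, plus strand), the motor that pulls pili back, at 4.79 (SE 0.20). The fallers included the pilus assembly gene BD_RS00530 and the cpaB gene BD_RS00535 of Flp pili, which fell by 2.42 (SE 0.15) and 2.04 (SE 0.14). Of 13 genes annotated for gliding motility, 8 rose and 2 fell, 5 and 0 of them under all 6 scalings. Gliding proteins U (BD_RS03805) and R (BD_RS03825) had log2 fold changes of 4.71 (SE 0.17) and 5.05 (SE 0.25). Another gene annotated as gliding protein U fell by 1.73 (SE 0.14), from 4265 ± 97.4 to 1282 ± 134 CPM, but was not called under all 6 scalings. In HEPES BD_RS03805 had only 39.8 ± 1.90 CPM. Camera did not call these 3 lists, with adjusted p of 0.0874, 0.585 and 0.123 after Benjamini-Hochberg adjustment, though it called chemotaxis by library size alone (adjusted p = 0.0439) and against RNase P RNA (adjusted p = 0.0395). With an estimated correlation under the TMM scaling, chemotaxis had an adjusted p = 0.829.

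**Figure D2:**
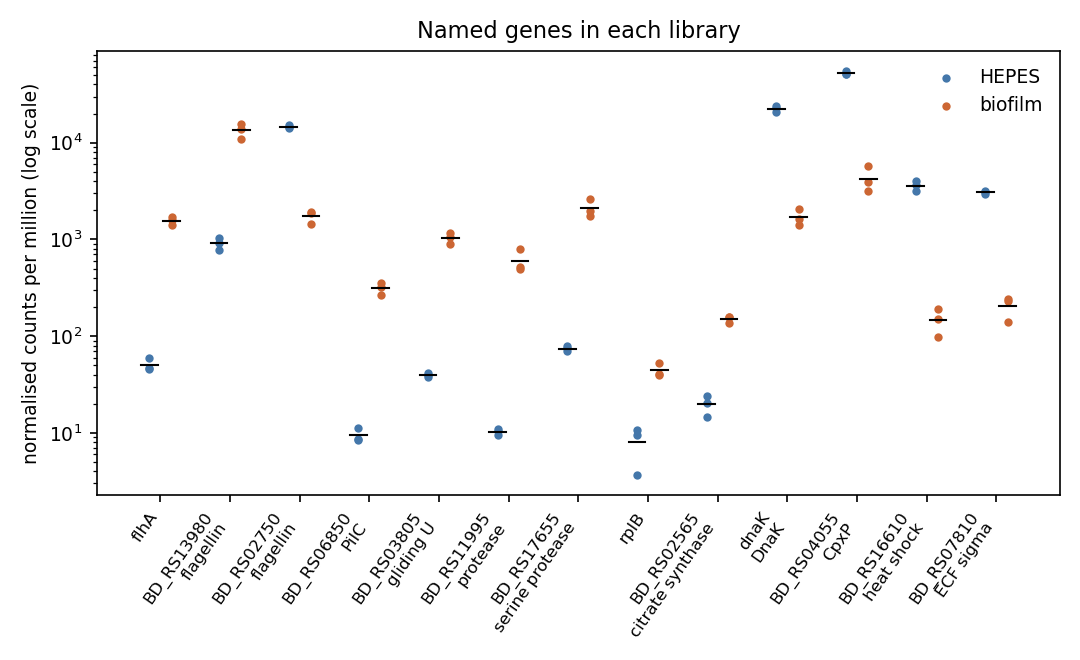
Points give TMM-scaled CPM on a log axis for 13 named genes in each of 3 HEPES and 3 biofilm libraries, and short lines give group means. The groups do not overlap for any of these genes, a property that the naming rule selected for. Means were 50.9 in HEPES against 1563 with the biofilm for flhA, and 22510 against 1706 for dnaK.

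Of 50 ribosomal protein genes, 43 rose and 0 fell (31 and 0 under all 6 scalings), with a median log2 fold change of 1.92 that ranged from 1.22 to 3.46 over the scalings. Camera called this list (Benjamini-Hochberg adjusted p = 0.0241), but the adjusted p was 0.911 with an estimated correlation, 0.119 with the stricter filter, 0.0767 and 0.0775 without biofilm replicate 1 or 2, 0.130 against RNase P RNA and 0.251 by library size alone. The genes of ribosomal proteins L2 (rplB) and S3 (BD_RS13595) rose by 2.48 (SE 0.29) and 2.79 (SE 0.25), from levels under 10 CPM in HEPES. Of 33 translation factor and tRNA ligase genes, 25 rose and 1 fell (18 and 0 under all 6 scalings), and the valyl-tRNA synthetase gene BD_RS02100 rose by 3.87 (SE 0.23). Camera gave that list an adjusted p of 0.104 with Benjamini-Hochberg adjustment, 0.0231 on gene ranks and 0.911 with an estimated correlation. Whether S. aureus reads left after filtering added to the conserved genes of the ribosomal and translation lists was not tested.

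In energy metabolism, 5 of 8 ATP synthase genes and 6 of 11 tricarboxylic acid cycle genes rose and 0 fell in either list, with 4 and 5 higher under all 6 scalings. The citrate synthase gene BD_RS02565 rose by 2.92 (SE 0.19), the succinate dehydrogenase gene sdhA by 2.57 (SE 0.22), and the ATP synthase beta subunit gene BD_RS17840 by 2.20 (SE 0.39). In HEPES BD_RS17840 had only 5.77 ± 4.16 CPM, from 11, 62 and 37 reads in replicates 1, 2 and 3. The respiratory chain list was mixed, with 5 of 15 genes higher, 6 lower (3 and 2 under all 6 scalings) and a median of -0.24 that ran from -0.93 to 1.27 over the scalings. Of 16 genes for purine and pyrimidine synthesis, 12 rose and 0 fell (8 and 0 under all 6 scalings), and of 17 for DNA replication, 6 rose and 7 fell (5 and 0), with the ribonucleotide reductase gene BD_RS09040 higher by 3.92 (SE 0.22). Camera called none of these lists, and S. aureus reads were not tested as a part of the rises.

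Among 97 protease and peptidase genes, 50 rose and 22 fell, of which 30 and 8 did so under all 6 scalings. BD_RS11995 (2543889 to 2544785, plus strand) had a log2 fold change of 5.87 (SE 0.23), an alkaline serine protease gene (BD_RS17655) 4.82 (SE 0.19) and a trypsin gene (BD_RS00160) 5.14 (SE 0.24), while the peptidase S74 gene BD_RS05190 fell by 3.00 (SE 0.16). Of 98 ABC transporter genes, 46 rose and 22 fell, and 32 and 2 did so under all 6 scalings. Camera called neither list, with Benjamini-Hochberg adjusted p of 0.244 and 0.300.

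The heat-shock gene BD_RS16610 (3526731 to 3527222, plus strand) fell by 4.62 (SE 0.23), dnaK (1228736 to 1230649, plus strand) fell by 3.72 (SE 0.18), and cpxP (BD_RS04055, 831842 to 832276, plus strand) fell by 3.63 (SE 0.21). The chaperone list as a whole had 5 genes higher and 7 lower of 15 (2 and 4 under all 6 scalings), with a median of -0.69 that reached 0.84 by library size alone, and a short gene annotated as DnaK, BD_RS17725, rose by 4.06 (SE 0.16). In the oxidative stress list, 5 of 14 genes rose and 5 fell (5 and 3 under all 6 scalings), with the thioredoxin gene BD_RS11275 lower by 3.16 (SE 0.16). Of 12 cobalamin, heme and iron genes, 1 rose and 7 fell, and 0 and 3 did so under all 6 scalings. BD_RS15765, annotated with the symbol hemA, fell by 3.07 (SE 0.19) and the hemY gene BD_RS05435 fell by 2.39 (SE 0.16). For the chaperone, oxidative stress and heme lists camera gave Benjamini-Hochberg adjusted p of 0.240, 0.492 and 0.0874.

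**Figure D3:**
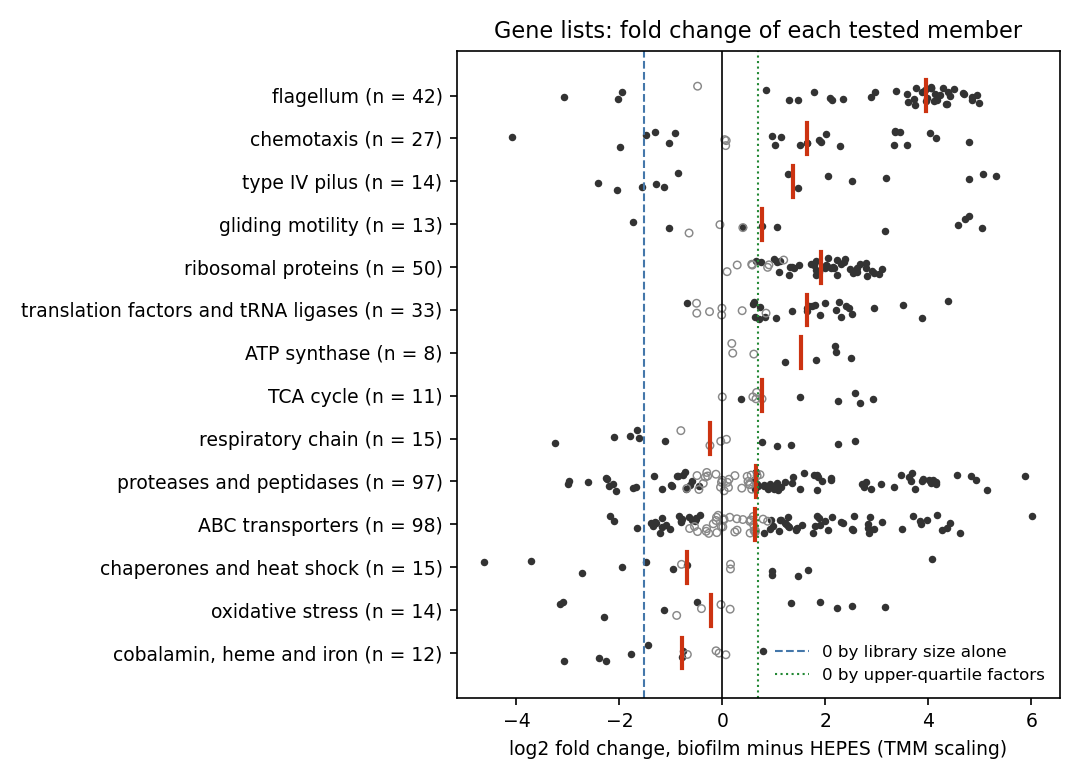
Each point is 1 tested gene of 14 lists, placed by its log2 fold change from HEPES to biofilm under TMM scaling, filled at an adjusted p under 0.05 and open otherwise, and red lines mark list medians. The flagellum median lies at 3.95, while 0 would lie at the dashed line by library size alone and at the dotted line with upper-quartile factors.

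Of 12 genes for RNA polymerase and sigma factors, 9 rose and 2 fell (9 and 1 under all 6 scalings). The sigma-E gene BD_RS03410 rose by 4.14 (SE 0.17) and the extracytoplasmic sigma factor gene BD_RS07810 fell by 3.91 (SE 0.20). In the list for cell division and shape, 11 of 19 genes rose and 3 fell (9 and 2 under all 6 scalings). The ftsE gene BD_RS00775 rose by 4.13 (SE 0.21) and the spoVG gene BD_RS12815 fell by 3.03 (SE 0.18). Camera called neither list. Genes with no known product were among the most abundant. BD_RS10115 fell by 2.65 (SE 0.16) from 53025 ± 1890 CPM in HEPES, and BD_RS16560 fell by 4.91 (SE 0.21) from 51896 ± 3111. BD_RS02445 rose by 1.65 (SE 0.27) to 14404 ± 7298 CPM with the biofilm.

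The remaining lists were not called by camera. Of 19 genes for TonB and Tol systems 13 were higher and 3 lower (11 and 1 under all 6 scalings), of 26 for peptidoglycan 12 and 4 (11 and 0), and of 37 for two-component systems 17 and 7 (11 and 4). Of 18 genes for protein secretion 8 were higher and 5 lower (7 and 2 under all 6 scalings), of 9 for lipopolysaccharide and outer membrane 5 and 4 (4 and 2), and of 24 for nucleases 9 and 10 (4 and 1). Of 30 genes for peptide and amino acid transport 13 were higher and 10 lower (9 and 3 under all 6 scalings), of 9 for glycolysis 3 and 1 (1 and 0), of 10 for fatty acid oxidation 3 and 2 (2 and 1), and of 11 for amino acid catabolism 3 and 2 (2 and 1). Of the rRNA and tRNA list 5 genes were tested, all of proteins named after those RNAs, 4 higher and 0 lower (1 and 0 under all 6 scalings). Adjusted over the list alone, the counts of higher and lower genes were equal to those over all genes for 25 of the 29 lists and differed by 1 gene for 4, the ribosomal list among them with 44 higher. Over the 6 scalings the median stayed above 0 for 15 lists and changed sign for 14. The scalings shift medians further up than down from TMM, so a median below 0 under all of them is harder to reach.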

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

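The scalings by library size, deposited TMM factors and RNase P RNA and the thinning were chosen after seeing the data. All 41 named genes kept their direction and call under every alternative run, 979 values in all. These genes were chosen from the 125 of 152 rule genes already called in the same direction under all scalings. For the scalings the result was therefore set by that choice and tested nothing. For the other alternatives the naming rule made it likely, since these genes had been chosen as called and without overlap between the groups. The rule genes that were not called in this way could not be named and are not in the tally. The total of genes called, 2282, and of those changed at least 2-fold, 1906, stayed within 1.5 times under every alternative. The split did not, and the cause was not tested beyond the scaling itself. For genes called higher and lower the counts were 2299 and 332 by library size alone and 2022 and 467 against RNase P RNA, and on RPKM, which also has no composition factor, 2292 and 353 with a pseudocount of 1, 2278 and 351 with 0.1, and 327 lower at a mean of at least 10. For changes of at least 2-fold they were 2070 and 163 by library size alone and 1793 and 290 against RNase P RNA, and on RPKM 1918 and 166, 2038 and 174, and 156 lower in the same order. Of the genes called under TMM, 1638 were called in the same direction by library size alone and 228 in the opposite one. Leaving out libraries gave 2038 to 2257 calls, 1167 to 1278 higher and 858 to 1035 lower, and 1815 to 1914 of at least 2-fold. Of the 2 lists called, both higher, 1 was left with the stricter filter and without biofilm replicate 1 or 2, where the ribosomal list was lost, while by library size alone and against RNase P RNA chemotaxis took its place. The count was 0 with an estimated correlation, where 0 lists had even an unadjusted p under 0.05. On gene ranks camera called 3 lists, with translation factors added. Fry, which does not compare a list with other genes, called 22 lists, 19 higher and 3 lower, and gave fatty acid oxidation, at a median of 0.0299, the opposite direction to camera. Median and camera direction differed in sign for 5 lists. The rRNA and tRNA genes held 0 counts, so leaving them out tested nothing. With the replicate number as a block 2312 genes were called. Libraries of the same number had correlations of deviations of 0.25, 0.22 and -0.11, and numbers 1 and 2 but not 3 correlated best with their own, so the numbers were not taken as pairs. The median HEPES count per gene was 29 to 36 reads against 175 to 228 with the biofilm, so low genes are less precise in HEPES.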

Other observations

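Product families and functional categories were grouped after seeing the data. All 6 genes annotated as cell wall surface anchor family proteins fell, with a median log2 fold change of -2.50 that stayed between -3.20 and -0.98 over the 6 scalings, and 5 of them fell under each scaling. Their share of all reads was 5.07% in HEPES and 2.71% with the biofilm. Fisher's exact test against the 1528 tested genes with a product gave this family a Benjamini-Hochberg adjusted p of 0.00504 for falling over 23 families. Of 12 LysR family regulators 8 fell and 1 rose, with an adjusted p of 0.0413, and of 35 genes called only transcriptional regulator 20 fell and 12 rose, with an adjusted p of 0.00504 by the same Fisher's exact test. Their medians, -1.32 and -1.05, reached 0.22 and 0.49 by library size alone. Under all 6 scalings 3 LysR family regulators fell and 0 rose, and 10 of the genes called only transcriptional regulator fell and 9 rose. Genes with the same product name need not be related, and genes are not independent replicates.

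Among eggNOG categories, cell motility had 49 genes higher and 12 lower of 67, and translation had 108 higher and 11 lower of 153. Camera called both, with Benjamini-Hochberg adjusted p of 5.51e-10 and 0.0230, against adjusted p of 0.740 and 0.934 with an estimated correlation. Of 6 flagellins, BD_RS02750 held 88.6% ± 1.87 of the flagellin reads in HEPES and 8.46% ± 2.16 with the biofilm, while BD_RS13980 held 5.50% ± 0.784 and 63.6% ± 2.65 (mean ± SD, n = 3).

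The tests below of the share of reads by total counts, by a few genes and by DNA as the whole cause, of the flagellum by scaling and by S. aureus reads, and of the flagellins by shared reads were chosen after the result was seen. Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real split, 1 of the 10, called 2282 genes and 1906 of at least 2-fold, and the highest of the others called 0. For lists, 7 of the 10 splits called as many as the real 2, and the highest of the others called 7. Those splits still part the conditions 2 against 1, which puts the difference between the conditions inside their groups. Their 0 gene calls therefore say little about chance. Camera called the flagellum list in 7 of the 9 other splits, with medians from -1.11 to 1.12 against 3.95, so its call alone does not set the real split apart.

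The higher flagellar transcripts with the biofilm may be a response to the biofilm culture. With no library from before the 4 h, a rise with the biofilm cannot be told apart from a fall in buffer. Scaling as the whole cause of the difference is argued against by the lower quartile of the list. It was 1.77 under the lowest scaling (95% bootstrap interval over genes 0.655 to 3.03). Misassigned flagellin reads are argued against by the lower quartile of 2.75 for the 36 other members (1.66 to 3.75). Reads from S. aureus, which has no flagellum, would favour conserved genes, yet the flagellum median exceeded that of the ribosomal list by 2.03 (1.58 to 2.37) and that of the translation list by more. The intervals resample genes as if they were independent and do not measure the spread between libraries. Genes of a list can move together, so the intervals may be too narrow. The biofilm and the liquid around it were not separated by this design, so which of them matters stays open.

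Most genes held a larger share of reads with the biofilm, 2325 of 3090 in all 9 pairs of libraries. Thinning to equal totals tested nothing, since shares are already divided by the total, and left the median log2 ratio at 1.58 or more. The 100 most abundant genes of a library held on average 75.6% of the reads in HEPES and 52.8% with the biofilm. Without the 100 genes most abundant over all 6 libraries, the median log2 ratio was still at least 0.806, which argues against those genes as the whole cause. The median over pairs fell from 1.78 to 1.04, and to 0.44 without 500, so the remainder depends on how many genes are left out. DNA in the biofilm libraries cannot be excluded as a part, because the level of the lowest 10% of genes reached 29.6% of the median gain, yet 63.4% of genes stayed higher in all pairs after that level was taken away. Whether cells in HEPES held less messenger RNA in total cannot be read from these counts.

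The flagellins moved in opposite directions, with 5 copies higher and 1 lower, and no biological explanation was tested for this. The flagellin that fell, BD_RS02750, had a log2 fold change of at most -1.54 under any of the 6 scalings, which argues against scaling. Reads shared in fixed proportions would keep copies that move alike together, but the log2 ratios of all 6 copies spanned at least 7.12 in pairs of libraries between groups and at most 1.69 within groups, which argues against such sharing alone as the cause. This span restates the fold changes already seen and does not bear on reads misassigned in other ways. How far sharing altered the size of the change of each copy stays open.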
